A study of Mus musculus with 12 samples.

How the data were processed

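RNA was taken from the hippocampus of mice with a conditional double knockout (DKO) and of control mice (WT), in libraries named Day and Night by the labels. The series description gives 9 a.m. and 9 p.m. as the hours of killing. There were 4 groups of 3 libraries, 12 in all. Per the labels' protocols, libraries were stranded (TruSeq) and were made from total RNA after removal of ribosomal RNA. The submitters' processing notes name genome build GRCm38.p6. The aligner, the quantifier, the annotation release and the number of reads per library are not given in the sources used here.

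The authors deposited 1 table per library with 21878 genes and 1 value per gene. The deposited values are FPKM, fragments scaled to transcript length and to the fragments of the library, a unit read from the values, since the file headers name only the sample. The values of a library summed to between 151059 and 175692, and the lowest value above 0 of a gene fell with transcript length (Spearman's rho = -0.718 over 792 genes of low level). Every gene carried a protein-coding type of RefSeq transcript accession (NM or XM), 114 genes had the biotype of a long noncoding RNA in the reference annotation, and 3964 genes were at 0 in all 12 libraries. Gene IDs of 21727 genes matched the reference annotation of the same build, from which coordinates, biotypes and names were taken. The symbols of 27 genes that a spreadsheet had turned into dates were restored from their gene IDs. The tables hold no counts, so depth is unknown and no counting interval can be given. The steps between the low values put the depth of the libraries at 0.92 to 1.05 times that of Day WT replicate 1.

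Before the data were examined, the tests, the gene lists, the rule for named genes and most alternatives were fixed. The first choice of test was a count model. Its stated replacement for FPKM was used, since the tables hold no counts. Values were transformed to log2(FPKM + 1), and the 12689 genes with FPKM of at least 0.5 in at least 3 libraries were tested with limma (version 3.58.1 in R 4.3.3). The fit had 1 mean per group over all 12 libraries and a variance prior with an intensity trend. The log2 differences printed are differences of log2(FPKM + 1), which shrink those of genes near or under 1 FPKM. The 7 comparisons were DKO against WT by day, DKO against WT at night, night against day in WT, night against day in DKO, the interaction of genotype and time, and the genotype and time differences averaged over the other factor. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, 2-sided. Every adjusted p of a single gene in the text comes from this limma fit. Nothing in the labels states that each library is a separate mouse, so the p-values measure only the spread between these samples. Group values are given as mean ± SD of FPKM over 3 libraries.

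The rule for named genes took, among others, Psen2 and up to 10 genes with the largest rise and 10 with the largest fall among those called. Those genes had a mean log2(FPKM + 1) of at least 1, no overlap between the libraries of both groups (not asked of the averaged comparisons) and a symbol that was not provisional. The rule also took up to 3 long noncoding RNAs per direction, up to 5 members of each gene list with the smallest p, all core clock members, and the 10 genes with the smallest interaction p. Genes named outside this rule are members of enriched terms and genes of single libraries, chosen after their values were seen.

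There were 25 gene lists with 449 entries. Those reported are Notch pathway, core clock, activity-induced immediate early genes, glucocorticoid-responsive genes, chaperones with cold-inducible RNA-binding proteins, disease-associated microglia, homeostatic microglia, complement, interferon response, antigen presentation, reactive astrocytes, astrocyte markers, excitatory neuron and postsynaptic genes, presynaptic vesicle genes, inhibitory interneurons, hippocampal subfield markers, adult neurogenesis and proliferation, oligodendrocytes and myelin, endothelial and mural cells, choroid plexus, neighbouring brain regions, blood, sex-linked genes and brain long noncoding RNAs. Some genes stand in more than 1 list. Each list was tested with camera (limma) at a preset correlation between genes of 0.01, 2-sided and adjusted over the lists of 1 comparison, and again with an estimated correlation. Camera tests whether a list moved relative to the other genes. Called members are also counted when adjusted over the list alone. Terms of the Gene Ontology (3001 with 10 to 500 tested genes) and pathways (295) were tested among called genes with a 1-sided hypergeometric test against all genes tested, adjusted per direction; for the averaged time comparison, proteasome, lysosome and ribosome pathways were tested again with median-of-ratios scaling and with the length trend removed, chosen after the results were seen.

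The alternatives fixed in advance were a pseudocount of 0.1, no filter beyond a value above 0 in 1 library, a filter at FPKM of at least 1 in at least 6 libraries, the replicate number as a block, a fit to only the groups compared, sample quality weights, an estimated correlation for the lists, and leaving out each library in turn. Added after seeing the data were median-of-ratios scaling, quantile normalization, removal of each library's trend with transcript length, and the choroid plexus level as a covariate. The counts were compared with those of other splits of the libraries, all 10 for 3 against 3 and 100 drawn for the others.

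The calling step was tested on simulated data, with known changes set in Day DKO. Each gene was drawn independently, around its mean over all 12 libraries and with its spread within the groups. The calling step recovered 63 of 99 genes changed 1.5-fold (63.6%) and 89 of 99 changed 2-fold (89.9%), and called 8 other genes among 12682. Variation shared between genes was not simulated, so these shares may be too favourable for the real libraries. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Long noncoding RNAs, which the series title names, were analysed only as far as the gene tables hold them; transcripts and other annotations were not analysed here.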

Results

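Hippocampal RNA was compared between DKO and WT mice in the day and at night, with 3 libraries in each of the 4 groups. The series title names circadian changes, memory that varies with the time of day and long noncoding RNA in the knockout mice. The FPKM of a library summed to between 151059 and 175692, with the number of reads unknown. Across genes, log2 values correlated at a Pearson's r of 0.9898 to 0.9947 in the 12 pairs of libraries of the same group and 0.9816 to 0.9934 in the 54 pairs of different groups; genes are not independent replicates.

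Psen2, a target of the knockout (gene ID 19165, chromosome 1, 180227004 to 180263467 in GRCm38.p6), was low in all 6 DKO libraries. By day it stood at 2 ± 0.756 FPKM in WT and 0.391 ± 0.123 in DKO (SD, n = 3), a log2 difference of -1.08 (limma, adjusted p = 0.00982). At night it stood at 3.38 ± 0.381 in WT and 0.477 ± 0.122 in DKO, a log2 difference of -1.57 (adjusted p = 0.000785). Psen2 checks the genotype labels. None of the 15 Notch pathway genes was called by day (1 higher and 3 lower when adjusted over the list alone; median -0.08, adjusted p = 0.072).

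**Figure D1:**
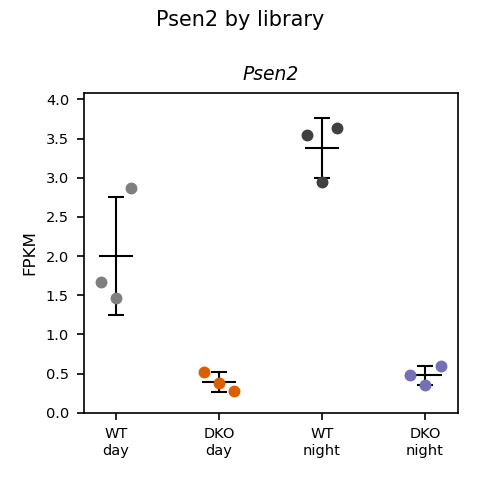
FPKM of Psen2 in each library, with 1 dot per library and bars at the group mean ± SD (n = 3). Psen2 lies between 0.275 and 0.594 in the 6 DKO libraries and between 1.47 and 3.64 in the 6 WT libraries.

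By day, several genes induced by neuronal activity were higher in DKO hippocampus. Nptx2, a secreted protein that gathers AMPA receptors at synapses, rose from 5.81 ± 0.808 to 14.1 ± 1.98 FPKM (log2 difference 1.15, adjusted p = 0.0159). Vgf, a neuropeptide precursor, rose from 22.3 ± 1.01 to 34.9 ± 2.3 (0.62, adjusted p = 0.00203), and the phosphatase gene Dusp5 (0.80), the neurotrophin gene Bdnf (0.39), the prostaglandin synthase gene Ptgs2 (0.58) and the neuronal transcription factor gene Neurod2 (0.51) rose with them. Of 29 activity-induced immediate early genes, 5 rose and none fell (7 higher and 1 lower when adjusted over the list alone), while the list as a whole did not pass (median 0.07, adjusted p = 0.19). The microglial chemokine gene Ccl6 (1.20), the signalling adaptor gene Blnk (0.85) and the astrocytic protease inhibitor gene Serpina3n (0.70) also rose.

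Several genes of vessel walls and of the extracellular matrix were lower in DKO by day. The smooth muscle genes Tagln (-1.25), Acta2 (-1.03), Myl9 (-0.95) and Myh11 (-0.85) fell, as did Crip1, a small LIM protein (from 20.7 ± 3.51 to 8.57 ± 1.77 FPKM, -1.19, adjusted p = 0.00401), the growth factor gene Igf2 (-1.14), the sulfate transporter gene Slc13a4 (-0.97) and the interferon-induced gene Ifitm3 (-0.81). Extracellular matrix was enriched among the genes that fell (8 of 146 tested, adjusted p = 0.00023), with Bgn (-0.50), Thbs1 (-0.59) and Pcolce (-0.88). So was TGF-beta signaling (5 of 63, adjusted p = 0.00122), with Bmp6 (-0.75) and Bmp7 (-0.48). Of 17 endothelial and mural genes, 3 fell (1 higher and 9 lower when adjusted over the list alone; median -0.23, adjusted p = 6.2e-08, and 0.27 with an estimated correlation). Choroid plexus genes, which mark tissue next to the hippocampus, had a median of -1.01 over 16 members, none called (11 lower when adjusted over the list alone; adjusted p = 3.9e-11, and 0.34 with an estimated correlation). Their most abundant member, Ttr, stood at 2060 ± 861 FPKM in WT and 855 ± 837 in DKO.

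In total, 150 of the 12689 genes tested were called by day, 101 higher and 49 lower, and 7 of them had a difference in log2(FPKM + 1) of at least 1, a scale on which low values change less than in FPKM. With the choroid plexus level as a covariate, added after the data were seen, 4 genes were called (Crip1, Phospho1, Psen2 and Vgf), and without a filter on low values 26. A fit to only the groups compared called 50, and quantile normalization gave 51 higher and 45 lower, median-of-ratios scaling 62 and 65 and removal of the length trend 66 and 67. The count was 60 without Day WT replicate 1 (22 higher and 38 lower), 14 without Day WT replicate 2 (6 and 8), 23 without Day DKO replicate 2, 19 without Day DKO replicate 3 and 85 without Night WT replicate 3. Of 33 called genes taken by the rule, Crip1, Psen2 and Vgf were called in all 22 settings run, and 30 lost their call in at least 1.

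At night, 3 genes were called, all lower in DKO. They were Psen2, Snapc1, a subunit of the complex that activates transcription of small nuclear RNA genes (4.15 ± 0.0612 in WT and 2.36 ± 0.101 FPKM in DKO, log2 difference -0.62, adjusted p = 0.00275), and Dhrs7, a dehydrogenase (9.89 ± 0.318 and 5.48 ± 0.671, -0.75, adjusted p = 0.014). All 3 also fell by day, Snapc1 by 0.47 and Dhrs7 by 0.56. Genes of disease-associated microglia had a median of 0.15 over 24 members, none called (8 higher when adjusted over the list alone; adjusted p = 2.8e-07, and 0.29 with an estimated correlation). Homeostatic microglia genes had a median of 0.23 over 14 members, none called (5 higher when adjusted over the list alone; adjusted p = 6.7e-08, and 0.26 with an estimated correlation). Night DKO replicate 1 lay no higher than the highest Night WT library in both lists, with a mean deviation of -0.17 for disease-associated microglia against 0.40 and 0.44 in the other Night DKO libraries and -0.12 to -0.09 in Night WT. The 7 blood genes, mostly globins, had a median of -0.49, none called (4 lower when adjusted over the list alone; adjusted p = 3.9e-07), and the list held with an estimated correlation (adjusted p = 0.026). At an unadjusted p under 0.05 there were 1165 genes, against 634 expected. By its sex-linked genes, Night WT replicate 1 differs in sex from the other libraries, so all comparisons that use Night WT mix sexes. Psen2 and Snapc1 were called in all 22 settings run, and Dhrs7 lost its call without a filter on low values, without Night DKO replicate 2 and without each of Night WT replicates 1, 2 and 3 (adjusted p up to 0.101). The night count was 38 without Night DKO replicate 1 (33 higher and 5 lower), 6 without Day WT replicate 1 and 5 without Day DKO replicate 2; it was 15 in a fit to only the groups compared, and 5 with a replicate block or with quality weights.

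The day and night genotype differences share no libraries. Of the 150 genes called by day, 121 (80.7%) had the same sign at night, against 55.2% of all genes, with a median ratio of the night to the day difference of 0.3. Across genes, Pearson's r was 0.358. No gene passed the test of the difference between the times (limma interaction, smallest adjusted p = 0.396, 1099 genes at an unadjusted p under 0.05), so the counts of 150 and 3 do not show that the genotypes differ more by day.

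Averaged over both times, several microglial and astrocytic genes were higher in DKO. Tyrobp, a signalling adaptor of microglia, stood at 19 ± 1.8 FPKM in WT and 38.9 ± 2.39 in DKO by day, and at 20.4 ± 2.29 and 45.5 ± 22.3 at night (averaged log2 difference 0.99, adjusted p = 0.0318). Cst7, a cathepsin inhibitor of activated microglia, stood at 0.0181 ± 0.0313 and 2.28 ± 0.335 by day, and at 0.169 ± 0.0332 and 4.03 ± 3.48 at night (1.67, adjusted p = 0.0387). The complement genes C1qa (0.83), C1qb (0.79) and C1qc (0.79) rose, as did Gfap, the astrocytic filament (0.79, adjusted p = 0.029). Of 24 disease-associated microglia genes 4 rose (9 when adjusted over the list alone; median 0.15, adjusted p = 5.6e-05, and 0.37 with an estimated correlation), and of 14 homeostatic microglia genes 5 rose (8 when adjusted over the list alone; median 0.20, adjusted p = 3.4e-08, and 0.24 with an estimated correlation). Of 9 complement genes, 4 rose and 2 fell (6 and 2 when adjusted over the list alone; median 0.36, adjusted p = 0.062). Night DKO replicate 1 held several of these genes near the WT level (Tyrobp 19.8, Gfap 34.4, Cst7 0.0274), against 56.6 and 60, 63.3 and 79.2, and 6.37 and 5.69 in the other Night DKO libraries. Without it, Tyrobp, Cst7, C1qc and Gfap were called at night, with log2 differences of 1.48, 2.59, 1.13 and 1.09. That library was singled out by its low values of such genes, so these calls give no independent support for a night difference.

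**Figure D2:**
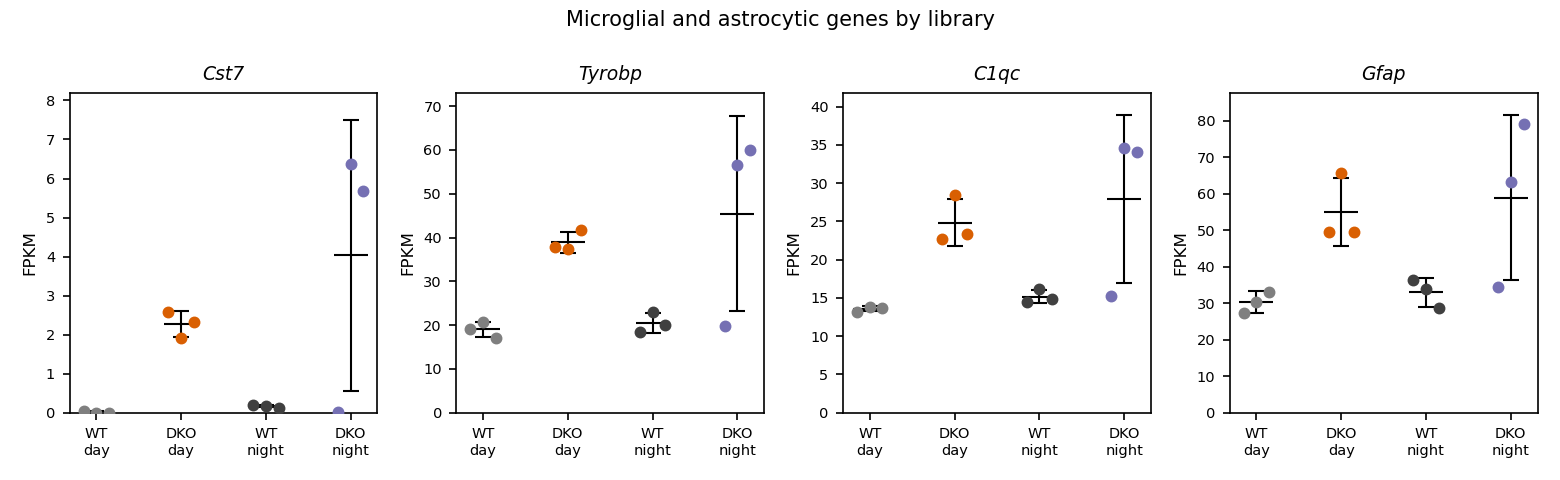
FPKM of Cst7, Tyrobp, C1qc and Gfap in each library, with 1 dot per library and bars at the group mean ± SD (n = 3). In Night DKO, replicate 1 lies near the WT libraries for each gene (Tyrobp 19.8 against 56.6 and 60 in the other Night DKO libraries).

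Several matrix, vessel, blood and antigen presentation genes were lower in DKO averaged over both times. Extracellular matrix was enriched among the genes that fell (17 of 146, adjusted p = 2.29e-11), with the collagen gene Col3a1 (-0.55) and the proteoglycan genes Lum (-0.57) and Bgn (-0.35). The MHC class II genes H2-Aa (-0.73), H2-Ab1 (-0.65) and H2-Eb1 (-0.62) fell, 3 of 15 antigen presentation genes (5 lower when adjusted over the list alone; median -0.12, adjusted p = 2e-05, and 0.24 with an estimated correlation). Of 17 endothelial and mural genes 4 fell (1 higher and 13 lower when adjusted over the list alone; median -0.19, adjusted p = 7.5e-11, and 0.14 with an estimated correlation), and of 7 blood genes 3 fell (4 when adjusted over the list alone; median -0.43, adjusted p = 1e-06, and 0.03 with an estimated correlation). Of 20 oligodendrocyte and myelin genes, 1 fell, Opalin at -0.40 (1 higher and 12 lower when adjusted over the list alone; median -0.20, adjusted p = 2.8e-08, and 0.35 with an estimated correlation). Choroid plexus genes had a median of -0.52 in the same comparison, none called (adjusted p = 1.6e-06, and 0.51 with an estimated correlation).

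The averaged genotype comparison called 238 genes, 127 higher and 111 lower, with 2 at a difference in log2(FPKM + 1) of at least 1. It called 24 without a filter on low values and 97 with the choroid plexus covariate (38 higher and 59 lower). More genes were also lower than higher with median-of-ratios scaling (138 higher and 180 lower), quantile normalization (126 and 154), the length trend removed (136 and 175) and without Day WT replicate 1 (69 and 124). The count was 93 without Day WT replicate 2, 126 without Day DKO replicate 2 (52 higher and 74 lower), 95 without Day DKO replicate 3 (45 and 50), 82 without Night DKO replicate 2, 89 without Night DKO replicate 3 (43 and 46), 80 without Night WT replicate 1 and 117 without Night WT replicate 3 (44 and 73). Of 50 called genes examined, Crip1, Dhrs7, Hbb-bt, Nptx2, Psen2, Snapc1 and Vgf were called in all 21 settings run, while the calls of Tyrobp, Cst7, C1qa, C1qb, C1qc and Gfap were each lost in some.

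In WT hippocampus, some of the genes that respond to glucocorticoids and some clock genes were higher at night. Tsc22d3, a leucine zipper protein induced by glucocorticoids, rose from 9.95 ± 1.25 to 21.7 ± 1.06 FPKM (log2 difference 1.06, adjusted p = 0.0339), and the kinase gene Sgk1 (1.00), the immunophilin gene Fkbp5 (0.59) and the transcription factor gene Klf9 (0.42) rose with it. Of 16 glucocorticoid-responsive genes 7 rose (13 when adjusted over the list alone; median 0.44, adjusted p = 5.8e-08, and 0.47 with an estimated correlation). The clock output factor Dbp rose from 8.5 ± 1.07 to 17.6 ± 1.07 (0.97, adjusted p = 0.0262), and Ciart (0.86), Per2 (0.44) and Nr1d2 (0.49) rose, while the clock activator Arntl fell (-0.29, adjusted p = 0.0429). These are 4 higher and 1 lower of 23 core clock genes (9 and 1 when adjusted over the list alone; median 0.12, adjusted p = 0.053). The cold-inducible gene Rbm3 (0.99) and the tetraspanin gene Tspan4 (0.76) rose, and the tight junction gene Cldn5 (-0.68), the radial glia and astrocyte gene Fabp7 (-0.51) and Sox9 (-0.42) fell. Of 7 blood genes 1 rose, Hbb-bt at 0.57 (6 when adjusted over the list alone; median 0.62, adjusted p = 0.0019, and 0.19 with an estimated correlation). Proteasome genes were enriched among those that rose (6 of 42, adjusted p = 0.0109).

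In WT, 212 genes were called between night and day, 192 higher and 20 lower at night, 1 of them with a difference in log2(FPKM + 1) of at least 1. The split depended on scaling: median-of-ratios scaling gave 22 higher and 33 lower, quantile normalization 26 and 46, and removal of the length trend 24 and 25, 49 in all. Without a filter on low values 64 were called, in a fit to only the groups compared 23, and with quality weights 418. The count was 1 without Day WT replicate 1, 41 without Day WT replicate 2, 132 without Day DKO replicate 3, 87, 64 and 79 without Night DKO replicates 1, 2 and 3, and 1 without each of the 3 Night WT libraries. Tspan4 was called in all 22 settings run, and 31 of the 32 called genes examined lost their call in at least 1. Night WT replicate 1 differs in sex from the other libraries by its sex-linked genes, so the WT time comparison mixes sexes.

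In DKO hippocampus, clock genes were among the genes with the largest differences between night and day. Dbp rose from 5.07 ± 1.77 to 20.7 ± 2.88 FPKM (log2 difference 1.87, adjusted p = 0.000194), and the clock repressors Nr1d1 (0.88), Nr1d2 (0.95), Ciart (1.05), Per2 (0.43) and Per3 (0.52) rose, while Arntl fell from 3.18 ± 0.265 to 1.54 ± 0.117 (-0.72, adjusted p = 0.000194). These are 6 higher and 1 lower of 23 core clock genes (12 and 2 when adjusted over the list alone; median 0.18, adjusted p = 1.4e-07, and 0.086 with an estimated correlation). Rhythmic process was enriched among the genes that rose (6 of 114, adjusted p = 0.000103). Rbm3 (0.98), Tspan4 (0.89) and Crip1 (0.96) rose, and Fabp7 (-1.18), the kinase gene Akt2 (-0.51) and Vgf (-0.37) fell. None of the 16 glucocorticoid-responsive genes was called (1 higher when adjusted over the list alone; median 0.18). Of 22 excitatory neuron and postsynaptic genes 1 fell (2 when adjusted over the list alone; median -0.10, adjusted p = 1.7e-05, and 0.41 with an estimated correlation). Choroid plexus genes had a median of 0.97 in this comparison, none called (11 higher when adjusted over the list alone; adjusted p = 1.4e-07, and 0.51 with an estimated correlation).

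In DKO, 38 genes were called between night and day, 23 higher and 15 lower, 3 of them with a difference in log2(FPKM + 1) of at least 1. The call counts were 21 without a filter on low values, 15 with the choroid plexus covariate, 69 with median-of-ratios scaling (27 higher and 42 lower), 63 with quantile normalization (24 and 39) and 60 with the length trend removed (24 and 36). Without Day DKO replicate 1 the split was 16 higher and 18 lower. The counts were 22 without Day DKO replicate 2, 21 without Day DKO replicate 3, 19 without Night DKO replicate 2 and 19 without Night DKO replicate 3. Dbp, Arntl, Nr1d1, Nr1d2, Fabp7, Tspan4, Rbm28, Akt2 and Coq10b were called in all 22 settings run. The WT and DKO time differences share no libraries: 195 of the 212 genes called in WT (92%) had the same sign in DKO, against 63.2% of all genes, and 16 genes were called in both, with the same sign, against 0.635 expected of independent lists. Both calls took each gene's spread from the same fit, so the lists are not independent and the expected number may be too low.

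**Figure D3:**
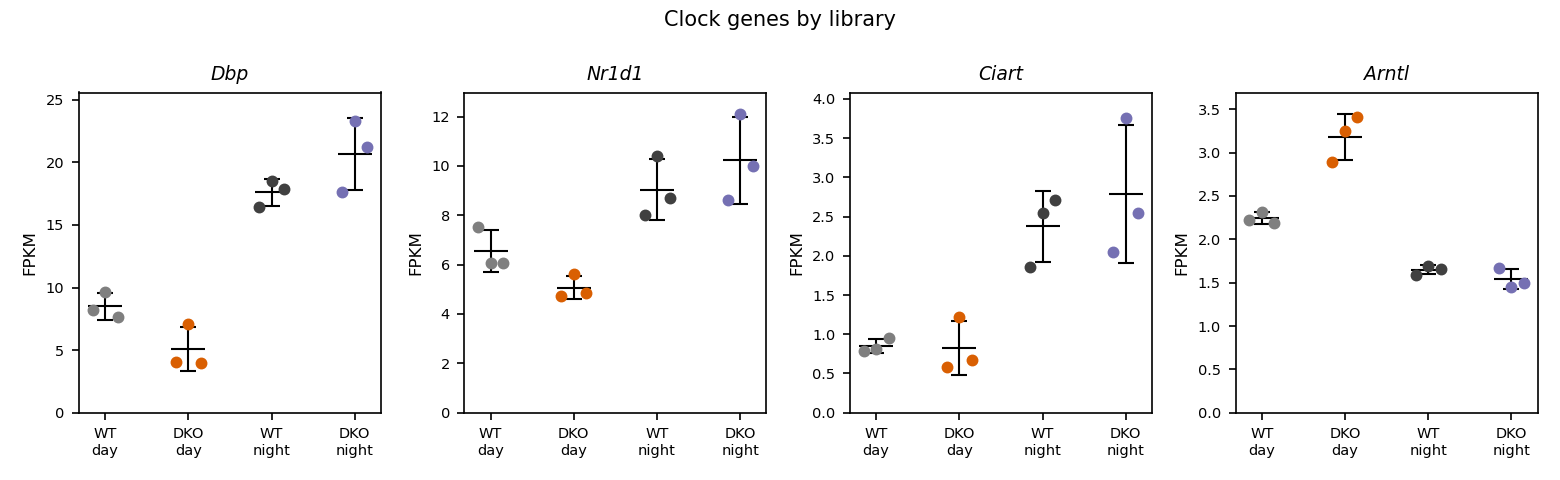
FPKM of the clock genes Dbp, Nr1d1, Ciart and Arntl in each library, with 1 dot per library and bars at the group mean ± SD (n = 3). Dbp means rise from 8.5 to 17.6 in WT and from 5.07 to 20.7 in DKO between day and night, and Arntl means fall from 2.25 to 1.65 and from 3.18 to 1.54.

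Averaged over both genotypes, 12 of 23 core clock genes rose at night and 1, Arntl, fell (15 and 2 when adjusted over the list alone; median 0.19, adjusted p = 5.6e-05, and 0.15 with an estimated correlation). Dbp rose by 1.42 (adjusted p = 8.91e-05), Ciart by 0.95, Nr1d2 by 0.72, Nr1d1 by 0.64, Per2 by 0.43 and Usp2 by 0.32. Of 16 glucocorticoid-responsive genes 8 rose (15 when adjusted over the list alone; median 0.30, adjusted p = 3.1e-06, and 0.49 with an estimated correlation), among them Tsc22d3 (0.81), the lipid droplet gene Plin4 (0.76) and Fkbp5 (0.40). Of 7 blood genes 5 rose (6 when adjusted over the list alone; median 0.50, adjusted p = 0.00078, and 0.15 with an estimated correlation), with Hbb-bt at 0.50. Tspan4 had the smallest p (0.82, adjusted p = 1.05e-05). Fabp7 (-0.85) and the basement membrane collagens Col4a1 (-0.40) and Col4a2 (-0.39) fell.

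Proteasome, lysosome and ribosome genes were overrepresented among the genes higher at night in the averaged comparison. Proteasome genes were enriched among those that rose (15 of 42, adjusted p = 3.62e-07), with Psma1 (0.22) and Psmb7 (0.25), as were lysosome genes (19 of 108, adjusted p = 0.000379), with Ctsl (0.27), and ribosome genes (19 of 129, adjusted p = 0.00355). Genes of dendrites were enriched among those that fell (16 of 416, adjusted p = 0.00112), with the postsynaptic scaffold genes Shank1 (-0.30), Shank2 (-0.17) and Shank3 (-0.23). Of 22 excitatory neuron and postsynaptic genes 4 fell and 1 rose (5 and 1 when adjusted over the list alone; median -0.07, adjusted p = 8.9e-05, and 0.50 with an estimated correlation). With median-of-ratios scaling, 7 proteasome (adjusted p = 0.00136), 8 lysosome (0.0448) and 8 ribosome genes (0.0805) were higher. With the length trend removed, 9 proteasome (2.43e-05), 9 lysosome (0.0353) and 7 ribosome genes (0.528) were higher and 1 lysosome gene lower, so ribosome genes were enriched in neither. The median of the lysosome genes was 0.08, against 0.05 for all genes, and 0.03 in both settings.

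This comparison called 770 genes, 659 higher and 111 lower at night, 3 of them with a difference in log2(FPKM + 1) of at least 1. Median-of-ratios scaling gave 207 higher and 282 lower, quantile normalization 231 and 345, removal of the length trend 245 and 249 (494 in all), and the choroid plexus covariate 372. The count was 243 without Day WT replicate 1, 382 without Day DKO replicate 1, 353, 487 and 374 without Night DKO replicates 1, 2 and 3, and 322, 424 and 353 without Night WT replicates 1, 2 and 3. Of 66 called genes examined, 30 were called in all 21 settings run, among them Dbp, Arntl, Ciart, Nr1d1, Nr1d2, Per2, Per3, Usp2, Fkbp5, Tsc22d3, Plin4, Psma1, Hbb-bt, Col4a1 and Col4a2.

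The interaction asked whether night and day differed by another amount in DKO than in WT. Limma called 0 genes, with 1099 at an unadjusted p under 0.05 against 634 expected, and 1 gene without Day WT replicate 3. The smallest adjusted p was 0.396. It was shared by the neurotrophin gene Bdnf (interaction -0.60), the lipogenic gene Thrsp (-0.77), the methionine adenosyltransferase gene Mat2a (-0.39), the pyruvate dehydrogenase kinase gene Pdk2 (0.46) and Crip1 (0.91). The interaction of Dbp was 0.89 (adjusted p = 0.463) and that of Arntl -0.42 (adjusted p = 0.396). The larger time differences of clock genes in DKO are therefore not shown gene by gene to differ from those in WT.

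Long noncoding RNAs were nearly absent from the tables, with 114 genes of that biotype, 14 of them tested. LOC108167886 rose in DKO by day from 0.317 ± 0.0189 to 0.8 ± 0.131 FPKM (log2 difference 0.45, adjusted p = 0.0161), also when adjusted over the list alone. No lncRNA was called in the 3 other pairwise comparisons by limma, where 1, 1 and 2 had an unadjusted p under 0.05. LOC108167886 lies too low to be tested under the stricter filter (0 lncRNAs called). Its day call was lost in a fit to only the groups compared and with the choroid plexus covariate (0 called each), and without Day WT replicate 2, Day DKO replicate 2 or Day DKO replicate 3 (0 called each). Of 25 brain long noncoding RNAs in the list only Snhg11 was tested; it stood at 44.5 ± 4.25 in WT and 44.1 ± 10.5 in DKO by day (-0.04, adjusted p = 0.916), and none was called when adjusted over the list alone.

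Other lists held few called genes between the genotypes by day. Antigen presentation genes had a median of -0.23 (1 of 15 lower, 5 when adjusted over the list alone; adjusted p = 5e-06, and 0.27 with an estimated correlation). Homeostatic microglia genes had a median of 0.20 (1 of 14 higher, 7 when adjusted over the list alone; adjusted p = 0.00011, and 0.34) and glucocorticoid-responsive genes one of 0.28 (1 of 16 higher, 4 when adjusted over the list alone; adjusted p = 0.00014, and 0.34). Of 22 excitatory neuron and postsynaptic genes 2 rose (3 when adjusted over the list alone; median 0.10, adjusted p = 0.02, and 0.57 with an estimated correlation; 0.06 without Day WT replicate 1, 0.13 without Day WT replicate 2 and 0.23 without Day DKO replicate 3). Of 23 core clock genes 1 was called, Arntl, higher in DKO by 0.36 (adjusted p = 0.0232; 1 higher and 4 lower when adjusted over the list alone). The clock list had a median of -0.04 (adjusted p = 0.019, and 0.34 with an estimated correlation; 0.07 without Day WT replicate 1 and 0.17 without Day DKO replicate 3). Arntl lost its call without Day WT replicate 1 or 2 and without Day DKO replicate 2 or 3. Of 24 disease-associated microglia genes 1 rose (1 when adjusted over the list alone; median 0.15, adjusted p = 0.062), and of 9 complement genes none was called (6 higher and 2 lower when adjusted over the list alone; median 0.44, adjusted p = 0.24). Among other neuronal lists, 1 of 20 hippocampal subfield markers rose (3 higher and 1 lower when adjusted over the list alone; adjusted p = 0.46), and none was called of 18 presynaptic vesicle genes (0 when adjusted over the list alone; 0.11), 16 interneuron genes (1 higher; 0.75), 13 genes of neurogenesis and proliferation (1 higher and 2 lower; 0.53) and 12 genes of thalamus and striatum (0; 0.11). Among 15 astrocyte markers none was called (2 higher when adjusted over the list alone; adjusted p = 0.11), while 2 of 16 reactive astrocyte genes rose (3 higher and 5 lower when adjusted over the list alone; 0.1). Of 17 chaperone and cold-inducible genes 1 rose (2 higher when adjusted over the list alone; adjusted p = 0.5). Of 16 interferon response genes 1 fell, Ifitm3 (1 lower when adjusted over the list alone; adjusted p = 0.0045, and 0.34 with an estimated correlation). Over all comparisons, camera called 54 list differences at the preset correlation, of which 2 held with an estimated correlation, the blood list at night and averaged over both times, both in DKO against WT.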

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

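The tests of a wrong genotype in Night DKO replicate 1, of uneven choroid plexus tissue and of the size of the day differences with a choroid plexus covariate were chosen after the results were seen.

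The time difference of 4 gene lists differed between DKO and WT by the interaction test (camera, preset correlation). Core clock genes had a median interaction of 0.05 over 23 members (adjusted p = 0.0019, and 0.79 with an estimated correlation). Choroid plexus genes had a median of 1 over 16 members (adjusted p = 4.5e-09, and 0.81 with an estimated correlation). Glucocorticoid-responsive genes had a median of -0.31 over 16 members (adjusted p = 0.0019, and 0.81 with an estimated correlation; 0.081 without Day DKO replicate 1 and 0.058 without Night DKO replicate 3). Antigen presentation genes had a median of 0.08 over 15 members (adjusted p = 0.026, and 0.81 with an estimated correlation; 0.094 without Day WT replicate 2, 0.055 without Day DKO replicate 3, 0.72 without Night DKO replicate 3 and 0.14 without Night WT replicate 2). None of the 4 held with an estimated correlation.

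Other splits of the libraries were fitted in the same way. For 3 against 3 there are 10 splits, too few for a share under 0.05. The real split called 150 genes by day (highest other 1), 3 at night (highest other 0), 212 between times in WT (highest other 0), 38 between times in DKO (highest other 1) and 1 lncRNA by day (highest other 0), and in each case 1 split, the real one, gave as many. For the averaged genotype comparison 1 of 100 splits, the real one, gave as many as 238 (highest other 82). In the averaged time comparison 1 of 100 gave as many as 770 (highest other 92). Both shares argue against chance in the assignment of libraries, at 1 in 100, the least that 100 splits can show. They say nothing about other differences between the groups, such as uneven choroid plexus tissue. For the interaction, with a real count of 0, all 100 of 100 splits give at least as many by construction, so they say nothing about chance. Of these, 10 splits gave more than the real one. Each of the 10 followed the real genotype or time in part, with an absolute correlation of at least 0.33 with 1 of them. The median correlations were 0.33 in these splits and in the 89 without calls. Genotype and time differences can thus enter such counts, and no further structure of the samples is shown. The highest, with 54 genes, set the 6 WT libraries against the 6 DKO libraries and so counted genotype differences; what parted the libraries in the next, with 48 genes, was not tested.

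Several microglial and astrocytic genes of Night DKO replicate 1 lay near the WT level, with Trem2 at 3.3 FPKM against 11.9 and 8.43 in the other Night DKO libraries, as did the neuronal gene Nptx2 (6.96 against 12.2 and 13.5); the microglial genes Aif1 (2.5) and Gpr34 (2.1) lay above all 6 WT libraries. Its Psen2 of 0.486 FPKM, far under the lowest WT library (1.47), argues against a WT library under a wrong name. A weaker knockout response of all genes is argued against by its mean shift of 0.15 over 135 of the genes called by day, a set without microglial genes and those of some chromosome regions, fixed before the test, beside 0.14 and 0.16 in the other Night DKO libraries. The cause stays open, and no biological explanation was tested for a single library.

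Choroid plexus genes were low in Day DKO, with Ttr at 786, 55.3 and 1720 FPKM in replicates 1 to 3 and at 2440, 2650 and 1070 in Day WT. Uneven choroid plexus tissue between dissections may be a cause, since members moved together between libraries of the same group (estimated correlation 0.91); a lower level in DKO mice themselves stays open as well. A single library cannot be told apart as the cause: without Day DKO replicate 2 the median was -0.58 instead of -1.01, with a standard error of the list difference of 0.47. Whether the choroid plexus level drives the day genotype calls cannot be told apart either: with it as a covariate 4 of 150 genes were called, which a test written in advance took as a sign that it does, while the differences kept a median ratio of 0.95. With the covariate, the median size of the log2 difference went from 0.44 to 0.40 and its median standard error from 0.08 to 0.10. The signs of 150 of 150 genes stayed the same, and 47.4% of the covariate's variance lay between groups. Over all genes tested, those at an unadjusted p under 0.05 in limma went from 2161 to 1183. What ended the calls was not tested further.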

How the results depend on the processing

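Median-of-ratios scaling, quantile normalization, the choroid plexus covariate and removal of the length trend were chosen after the results were seen. Without a filter on low values, 26 genes were called by day, 64 between times in WT, 21 between times in DKO and 24 for the averaged genotype. A fit to only the groups compared, with fewer libraries behind the spread, called 50 by day, 15 at night, 23 in WT and 0 lncRNAs, and the stricter filter 0 lncRNAs. The replicate block and quality weights each called 5 at night, and quality weights 418 in WT. The numbers were not taken to pair the libraries: 7 of 18 correlations between libraries of the same number exceeded 0.1 (from -0.116 to 0.247). All 3 pairs of Day DKO with Night WT did (0.168, 0.247 and 0.171), groups not compared directly, and in none of the 4 pairwise comparisons did all 3. Median-of-ratios scaling called 55 in WT, 69 in DKO and 489 for the averaged time difference, with 42.3% higher at night against 85.6% as deposited. Quantile normalization called 96 by day, 72 in WT and 63 in DKO. Removal of the length trend called 49 in WT, 60 in DKO and 494 for the averaged time difference. The choroid plexus covariate called 4 by day, 15 between times in DKO, 97 for the averaged genotype, 372 for the averaged time difference and 0 lncRNAs. It turned the direction of the choroid plexus list, by construction, in the DKO time (adjusted p = 0.4), averaged genotype (0.98) and averaged time (0.097) comparisons, and that of Ttr by day (0.03). With an estimated correlation 2 list calls held. The causes of the other changes were not tested.

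Leaving out 1 library gave 14 to 205 genes by day, 2 to 38 at night, 1 to 214 between times in WT, 19 to 55 in DKO, 0 to 1 for the interaction, 80 to 255 for the averaged genotype, 243 to 853 for the averaged time difference, 0 to 1 lncRNA and 49 to 68 list calls. The sex-linked list, called in 2 comparisons, ranged from an adjusted p of 9.9e-05 to 0.41 (night genotype) and from 4.7e-05 to 0.79 (WT time), and turned its direction without Night WT replicate 1. Over the 54 list calls and 12 libraries left out in turn, 580 values kept direction and threshold, 66 passed the threshold no more and 2 turned. A pseudocount of 0.1 kept all counts within 1.5 times. The DESeq2 test, edgeR with median-of-ratios factors and fits per transcript were not run, for want of counts and transcripts; median-of-ratios scaling was applied to the FPKM only. Without counts, the limit that depth sets on genes of low level is unknown.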

Other observations

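The sex-linked list was fixed before the data were examined, and the single genes and libraries named in this part were chosen after their values were seen. Sex-linked genes set 1 library apart. Ddx3y, a helicase gene of the Y chromosome, stood at 0.0225 FPKM in Night WT replicate 1 and between 6.83 and 8.56 in the other 11 libraries, and Kdm5d and Uty stood at 0 and 0.00224 there. The labels give no sex. By these genes, 1 of the 3 Night WT libraries differs in sex from the rest, so comparisons that use this group mix sexes. The 4 tested sex-linked genes had a median of -0.60 between night and day in WT (none called, none when adjusted over the list alone; camera, adjusted p = 0.009, and 0.65 with an estimated correlation), with 0.79 without that library. They had a median of 0.63 between genotypes at night (none called; adjusted p = 0.021, and 0.67 with an estimated correlation), with 0.41 without that library and 0.055 without Night DKO replicate 3.

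The ribosomal protein gene Rpl34 and its processed copy Rpl34-ps1 went opposite ways between libraries. In all 6 DKO libraries Rpl34 stood between 85.1 and 99.5 FPKM and Rpl34-ps1 between 31 and 45.8. In WT, Day replicates 1 and 3 and Night replicates 1 and 3 held Rpl34 at 49.8, 2.27, 56.3 and 49.5 and Rpl34-ps1 at 189, 329, 210 and 219, while Day replicate 2 and Night replicate 2 held 90 and 113 and 42.6 and 40.9. Reads can be split between near-identical copies, so the level of either gene is uncertain. Why the libraries differed was not tested. The pituitary hormone gene Gh reached 29 FPKM in Day WT replicate 2 and 23.2 in Night DKO replicate 1, and was at 0 in Day WT replicate 3 and Day DKO replicate 3. Gapdh stood at only 2.57 to 4.38 FPKM. Its family of processed copies may make that value uncertain, which was not tested.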
